A study of Mus musculus with 6 samples.

How the data were processed

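RNA was sequenced from LSK cells of mouse bone marrow, the fraction that carries no mature lineage markers and displays both Sca1 and c-Kit on its surface. This fraction holds the blood stem cells and the early multipotent progenitors. The mice carried the Jak2 V617F allele in homozygous form together with Mx1Cre, a recombinase driven by an interferon-responsive promoter. They received vehicle (PBS, per the labels) or TP-3654, named a Pim1 inhibitor in the series title, at 150 mg/kg/day for 6 weeks. Each group has 3 libraries, which the design text calls biological replicates, so p-values measure the spread between these 3 samples per group. Per the labels' protocols, lineage-positive cells were depleted on magnetic beads before the sort, and libraries were made from poly(A)-selected RNA with an NEBNext Ultra II kit.

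The authors deposited a table of whole-number read counts per Entrez gene, with 1 column per library and no normalization. They also deposited a table of their own comparison. Per the file headers, its signal values are deposited means of normalized counts per gene over all libraries, made by the authors by dividing counts by size factors. It also holds a log2 fold change with its standard error, deposited per gene with the sign of TP-3654 over vehicle when set against the counts. The deposited score of each gene is a Wald statistic, equal to the fold change over its standard error. The deposited p-values come as a raw and an adjusted p-value per gene, per the file headers. HISAT2 2.1.0, SAMtools 1.9.0 and DESeq2, and the builds mm10 and GRCm38, are named in the submitters' processing notes. The read counter, the gene annotation and the strand setting are not given in the sources used here. Reads from overlapping genes and from antisense pairs therefore cannot be told apart, and genes with near-identical copies are uncertain.

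Gene symbols came from the authors' deposited table and from a RefSeq gene table of GRCm38.p6, which is the submitters' build and which also gave gene coordinates. Of 15845 Entrez genes in the count table, 15839 received a symbol. Library totals ran from 20582057 to 25315596 counts. A count of 3 corresponded to 0.119 to 0.146 CPM (counts scaled to a common library total), which sets the level below which a gene was not detectable at this depth.

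The comparison of TP-3654 with vehicle used edgeR 4.0.16 in R 4.3.3 on the deposited counts. It applied TMM factors, the filterByExpr filter, a robust quasi-likelihood fit and the quasi-likelihood F test with Benjamini-Hochberg adjusted p-values, called under 0.05 (the false discovery rate, FDR). The filter kept 13149 genes and removed 2696, which together held 0.067% of the counts. CPM values are TMM-scaled and are given as the mean ± SD of 3 libraries. Log2 fold changes are TP-3654 minus vehicle with a standard error (SE). In edgeR the SE was derived from the test, as the absolute log2 fold change over the square root of the F statistic. Alternatives were DESeq2 1.42.0, limma-voom with and without sample weights (limma 3.58.1), other scalings, other low-count filters, a fit without the robust option, a block for the replicate number and fits without each library in turn.

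A total of 41 gene lists were written down before the data were examined, and 39 had at least 5 tested members. The mitochondrial-encoded genes had 0 tested members, since the count table lists none of them, and the sex-linked genes had 1. Each list was tested with camera at its preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. Members were also counted after Benjamini-Hochberg adjustment over the list alone. The genes named were fixed by a rule made before the data were examined. The rule takes the 12 genes per direction with the smallest p among those called, with groups that do not overlap, a mean log2 CPM of at least 1 and no predicted or pseudogene symbol. With fewer than 12 called, it takes all called and fills up to 6 per direction by smallest p, named as not passing. It adds Pim1, Pim2, Pim3 and Jak2, up to 4 members of each list with the smallest p, members needed to say what moved in a called list, the sex-linked genes, and the sort markers Ly6a (Sca1) and Kit. Genes outside the rule are named as chosen after their values were seen.

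To measure how much sequence a gene shares with other loci, all 31-mers of its annotated transcripts were looked up among those of every other locus of a GENCODE annotation of GRCm38. A value was found for 95.6% of tested genes. A gene was taken as unique in sequence when at most 1% of its 31-mers were shared, which held for 8161 tested genes. The fits on those genes were added after the data were examined. The edgeR and camera steps were tested on simulated counts with the real means, library sizes and dispersions for 13149 genes. Of 100 genes changed 2-fold, 79 were recovered, and of 100 changed 4-fold, 96. Of 12909 unchanged genes, 18 were called. Simulated genes varied independently, changed genes were drawn only from those above a minimum mean count, and no library was made to stand apart. The recovery is therefore not the power of the real comparison, and camera's correlation setting was not tested by it. All 10 splits of the 6 libraries into groups of 3 were fitted in the same way.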

Results

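The data are RNA-seq counts of 6 libraries of LSK cells from mice homozygous for Jak2 V617F, 3 given vehicle and 3 given the PIM kinase inhibitor TP-3654 for 6 weeks. Library totals were 24783920, 22557781 and 22210021 counts for vehicle replicates 1 to 3, and 20854009, 25315596 and 20582057 counts for TP-3654 replicates 1 to 3. Between 15138 and 15529 genes had at least 1 count in a library. Xist was counted at 12631 to 34675 per library and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty at 0 to 2, so all 6 libraries carried the counts of female mice. The design asks how PIM inhibition alters gene expression in the stem and progenitor cells of this model of myeloproliferative neoplasm.

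In the TP-3654 libraries 25 of 34 granulocyte-monocyte progenitor genes were lower and 19 of 45 stem cell genes higher than in vehicle, adjusted over the list alone, with 0 of either passing in edgeR over all genes. The 25 became 4 without vehicle replicate 1 or TP-3654 replicate 1, 8 without vehicle replicate 2, 12 without TP-3654 replicate 3 and 14 without vehicle replicate 3. At an unadjusted p under 0.05 there were 27 and 23, and DESeq2 called 19 and 20. Both lists were called by camera with its preset correlation and neither with an estimated one (adjusted p = 0.45 with an estimated correlation for each). Cebpa, the transcription factor that drives myeloid commitment, stood at 161 ± 8.58 CPM (SD, n = 3) in vehicle and at 88.4 ± 27.5 in TP-3654 libraries. Mpo, the myeloperoxidase of primary granules, stood at 7484 ± 797 and 2839 ± 1642 CPM. The stem cell transcription factors Hlf (66.5 ± 13.8 against 126 ± 6.92 CPM) and Mecom (2.05-fold) were also higher.

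Across all 13149 tested genes, edgeR called 0 genes at an FDR of 0.05, and the smallest adjusted p was 0.0701. At an unadjusted p under 0.05 there were 2244 genes, 1344 higher and 900 lower, or 17.1% of those tested. On the same counts DESeq2 called 657 genes, 401 higher and 256 lower, limma-voom called 0, and limma-voom with sample weights called 147, 101 higher and 46 lower. The 3 TP-3654 libraries lay above or below all vehicle libraries at 25.9% of genes, where chance gives 10%. Without TP-3654 replicate 3 edgeR called 31 genes, 19 higher and 12 lower. Without TP-3654 replicate 2 it called 18, without TP-3654 replicate 1 it called 7, and without any 1 vehicle library it called 0. In a fit added after the data were examined, restricted to 8177 genes with unique sequence, all 6 libraries together gave 77 higher and 44 lower genes.

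None of the 12 named genes, the 6 per direction with the smallest p under the rule, passed over all genes in edgeR with all 6 libraries. DESeq2 called all 12, but they were picked by edgeR p on the same counts, so this is no separate support. Of the 657 DESeq2 calls, 648 had an unadjusted p under 0.05 in edgeR. On 5 libraries edgeR called 10 of the 12 named genes without TP-3654 replicate 3, leaving out Slc2a6 and Anxa3. Lrrn4, a leucine-rich repeat membrane protein on chromosome 2 (132866686 to 132894010, GRCm38), stood at 2.29 ± 0.149 CPM in vehicle and 8.26 ± 0.833 in TP-3654 libraries, 3.60-fold higher (log2 fold change 1.85, SE 0.23, adjusted p = 0.0701). Col16a1, a collagen chain on chromosome 4 (130047817 to 130099277), was 3.61-fold higher. Rnf150 was 2.79-fold, Gimap5 2.55-fold, the basement membrane collagen Col4a2 2.26-fold and Pglyrp2, which cleaves bacterial peptidoglycan, 2.01-fold higher. Lgals1, which encodes galectin 1 and lies on chromosome 15 (78926725 to 78930465), had the smallest p, with a log2 fold change of -1.29 (SE 0.16, adjusted p = 0.0701) and a level 2.44-fold lower with TP-3654. Ptgr1 was 2.76-fold, Anxa3 2.41-fold, the mitochondrial choline dehydrogenase Chdh 2.36-fold, the glucose transporter gene Slc2a6 2.07-fold and Ncf1, a subunit of the phagocyte NADPH oxidase, 1.71-fold lower. Without TP-3654 replicate 3, Lgals1 had an adjusted p of 0.0286 and Lrrn4 one of 0.0299.

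**Figure D1:**
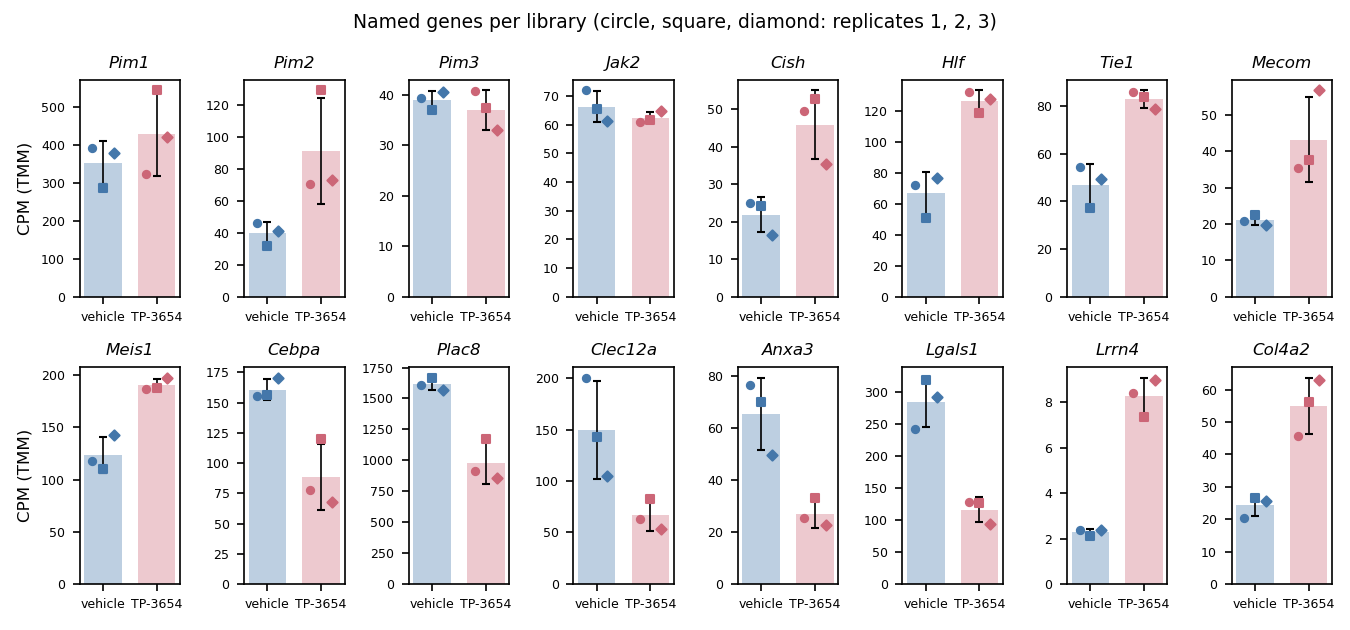
CPM (TMM-scaled, y axes from 0) of 16 named genes in 3 vehicle and 3 TP-3654 libraries. Bars are group means, error bars the SD and symbols the libraries; Hlf, Tie1, Mecom and Meis1 lay higher and Cebpa, Plac8, Clec12a and Anxa3 lower in each TP-3654 library than in any vehicle library, while Pim1, Pim3 and Jak2 overlapped between groups.

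Among the Pim genes and the JAK-STAT pathway, Pim2 (X chromosome, 7878306 to 7883432) was 2.29-fold higher. It stood at 39.8 ± 7.13 CPM in vehicle and 91.2 ± 33.2 with TP-3654 (log2 fold change 1.20, SE 0.26, adjusted p = 0.107). Pim1 (chromosome 17, 29490785 to 29496111) had a log2 fold change of 0.28 (SE 0.20, adjusted p = 0.479), Pim3 one of -0.08 (SE 0.13) and Jak2 one of -0.09 (SE 0.11), all with groups that overlapped. In the list of 20 JAK-STAT components, edgeR called 3 higher and 1 lower adjusted over the list alone and 0 over all genes. Of that list 7 had an unadjusted p under 0.05 and DESeq2 called 4. Pim2, Jak3 (log2 fold change 0.58) and Jak1 (0.39) rose and the interleukin 3 receptor chain Il3ra (-0.67) fell adjusted over the list alone. None passed without vehicle replicate 2, and only 1 without vehicle replicate 3. Of 23 STAT5 target genes, Cish, a feedback inhibitor of cytokine signalling (log2 fold change 1.07, SE 0.21), and Pim2 rose adjusted over the list alone. With edgeR 0 passed over all genes, 6 had an unadjusted p under 0.05 and DESeq2 called 2. None passed without vehicle replicate 2 or 3. Socs2 (0.73) and Dusp5 (0.56) were higher in each TP-3654 library without passing. Neither list passed camera (adjusted p = 0.22 and 0.0822). Without TP-3654 replicate 1 the JAK-STAT list was called higher (adjusted p = 0.0487, with 5 members higher and 1 lower), and without TP-3654 replicate 3 the STAT5 list was (adjusted p = 0.000145, median 0.29). Neither call held (adjusted p = 0.74 and 0.33 with an estimated correlation). The sort markers did not pass over all genes: Kit had a log2 fold change of 0.43 (SE 0.13, adjusted p = 0.166) and Ly6a, which shares sequence with neighbouring Ly6 genes, one of 0.28 (SE 0.19, adjusted p = 0.464). Kit still lay higher in each TP-3654 library (436 to 581 CPM) than in any vehicle library (365 to 377 CPM). The authors' deposited table calls Kit higher (deposited adjusted p = 0.0194), and Ly6a overlapped between groups. Xist had a log2 fold change of 0.84 (SE 0.25, adjusted p = 0.176).

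Among the cell type lists, the granulocyte-monocyte progenitor genes fell as a list (median log2 fold change -1.12, camera adjusted p = 3.37e-27; adjusted p = 0.45 with an estimated correlation). Of 34 members, 25 fell and 0 rose adjusted over the list alone. Over all genes edgeR called 0, 27 had an unadjusted p under 0.05 and DESeq2 called 19. Besides Anxa3, Cebpa and Mpo they included Plac8 (log2 fold change -0.72, SE 0.15), the lectin receptor Clec12a (-1.17, SE 0.26) and Ap3s1 (-1.04, SE 0.19). Leaving out 1 library, which lowered that count to 4 without vehicle replicate 1 or TP-3654 replicate 1, gave a list median between -1.33 and -0.89. The stem cell genes rose as a list (median 0.55, camera adjusted p = 4.19e-13; adjusted p = 0.45 with an estimated correlation). Of 45 members, 19 rose and 0 fell adjusted over the list alone, against 0 over all genes, 23 at an unadjusted p under 0.05 and 20 called by DESeq2. They included Hlf (log2 fold change 0.92, SE 0.15), the receptor tyrosine kinase gene Tie1 (0.82, SE 0.15), Mecom (1.04, SE 0.19), Txnip (0.64, SE 0.12) and the homeobox gene Meis1 (0.63, SE 0.12). Leaving out 1 library gave 14 to 23 higher members, with 1 lower member only without TP-3654 replicate 1.

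**Figure D2:**
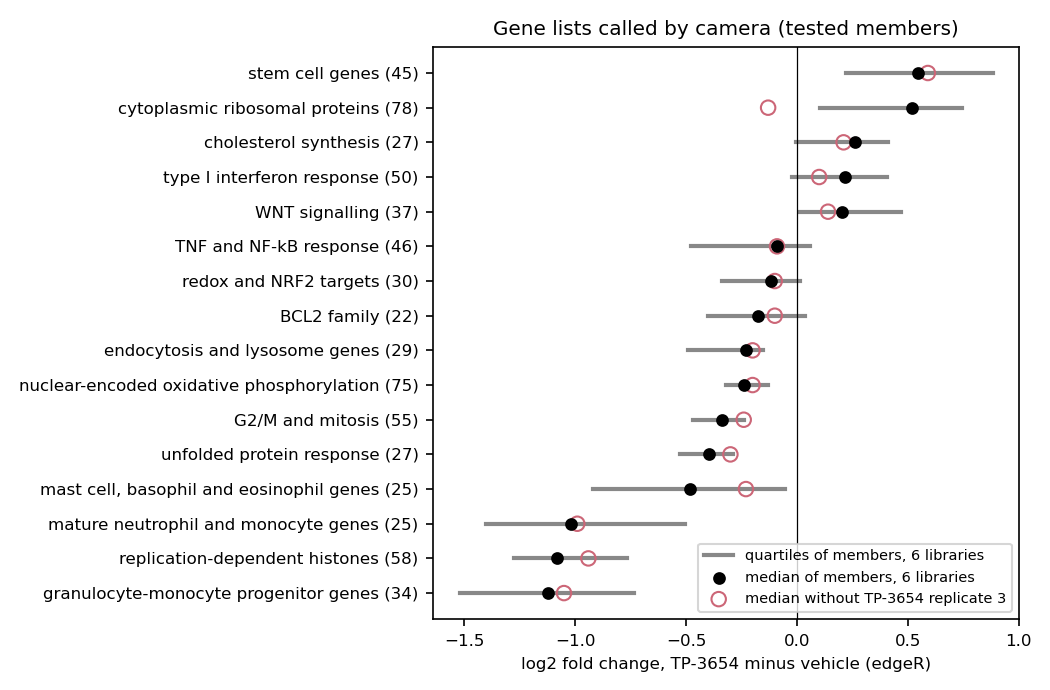
Log2 fold change (x axis, TP-3654 minus vehicle) of the 16 gene lists called by camera, with the number of tested members in brackets. Black points are list medians, grey bars the quartiles of the members and open circles the medians without TP-3654 replicate 3, and the median of the ribosomal protein list was 0.52 with that library and -0.13 without it.

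The mature neutrophil and monocyte genes, whose products belong to cells outside the sort, had a median of -1.02 (camera adjusted p = 0.000187; adjusted p = 0.76 with an estimated correlation). Vehicle replicate 1 decided that call: without it the median was -0.07 and the adjusted p 0.318, and without TP-3654 replicate 1 the adjusted p was 0.0566. On genes with unique sequence the call was lost at nearly the same median (-1.03, adjusted p = 0.0625). S100a8 stood at 39.0 CPM in vehicle replicate 1, at 0.450 and 0.458 in the other vehicle libraries and at 0.463 to 9.21 in TP-3654 libraries. Of 25 members, Pglyrp1 (log2 fold change -1.13, SE 0.21) fell adjusted over the list alone, 0 passed over all genes and 5, among them Trem1 (-0.88), had an unadjusted p under 0.05, while DESeq2 called 3. None passed without vehicle replicate 2 or TP-3654 replicate 1, and 5 did without TP-3654 replicate 2. The mast cell, basophil and eosinophil genes fell as a list (median -0.48, camera adjusted p = 0.000127; adjusted p = 0.58 with an estimated correlation), to a median of -0.23 without TP-3654 replicate 3, where the call was lost on genes with unique sequence (median -0.21, adjusted p = 0.0901). Of its 25 members edgeR called 0 adjusted over the list alone and 0 over all genes, 6 had an unadjusted p under 0.05 and DESeq2 called 4. The mast cell proteases Tpsb2 (log2 fold change -2.27) and Cma1 (-2.25) and the regulator Lmo4 (-0.57) were lower in each TP-3654 library than in any vehicle library. For Tpsb2 this was narrow and at a low level. Its CPM was 0.591, 3.29 and 3.21 in vehicle replicates 1 to 3 and 0.348 to 0.562 in TP-3654 libraries. Without vehicle replicate 1, 2 members fell adjusted over the list alone, without TP-3654 replicate 2, 3 did, and without TP-3654 replicate 3, 3 fell and 1 rose.

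The remaining cell type lists did not pass camera with all 6 libraries. In the lymphoid-primed list (median 0.19, adjusted p = 0.0822), Flt3 (log2 fold change 0.78), the cytokine receptor of early lymphoid progenitors, and Il7r (1.51) rose and Emb (-0.55) fell adjusted over the list alone. In edgeR 0 of 26 passed over all genes, with 7 at an unadjusted p under 0.05 and 4 called by DESeq2. Without vehicle replicate 1, vehicle replicate 2 or TP-3654 replicate 2 none of them passed, without TP-3654 replicate 1 only 1 did, and without TP-3654 replicate 3, 5 rose and 2 fell. Camera called that list higher without vehicle replicate 1 (adjusted p = 0.0351) or TP-3654 replicate 3 (adjusted p = 0.00314) at the preset correlation (adjusted p = 0.83 and 0.58 with an estimated correlation). In the macrophage and dendritic cell list (median 0.11, adjusted p = 0.608), Runx2 (0.42), Flt3 and Tcf4 rose and the chemokine receptors Cx3cr1 (-1.18) and Xcr1 (-1.77) and Ms4a6c (-0.81) fell adjusted over the list alone. Tcf4 and Ms4a6c lay outside the naming rule and were chosen after their values were seen. In edgeR 0 of 29 passed over all genes, with 8 at an unadjusted p under 0.05 and 6 called by DESeq2. Without vehicle replicate 1 that list was called higher (median 0.80, adjusted p = 2.66e-06; adjusted p = 0.42 with an estimated correlation), with 13 members higher and 3 lower. Leaving out vehicle replicate 2 none passed, and leaving out TP-3654 replicate 2 only 1 did, lower. Leaving out TP-3654 replicate 3, 4 rose and 2 fell among the members tested with all 6 libraries, but 1 fell and 0 rose with the 30 members that passed the filter then. In the stromal and endothelial list (median -0.04, adjusted p = 0.932), Pdgfrb (0.89) and Alpl (1.80) rose and Plvap (-1.27) fell adjusted over the list alone. In edgeR 0 of 19 passed over all genes, with 5 at an unadjusted p under 0.05 and 2 called by DESeq2. Leaving out any 1 vehicle library, none passed, and leaving out TP-3654 replicate 2, 3 rose and 2 fell. By edgeR 0 members passed, adjusted over the list alone or over all genes, among 43 erythroid genes (median -0.17, adjusted p = 0.0921), 41 megakaryocyte genes (-0.15, adjusted p = 0.625), 10 B cell genes (0.21, adjusted p = 0.976) and 28 T, NK and innate lymphoid genes (0.50, adjusted p = 0.0692). At an unadjusted p under 0.05 these lists had 2, 7, 1 and 13 members, and DESeq2 called 0, 3, 0 and 4. Slc25a37 (0.36), Sla2 (0.94), Ly6d (1.26) and Rora (1.20) had the smallest p in each. The erythroid median was 0.14 without TP-3654 replicate 3 and 0.07 without vehicle replicate 1, and the list was called lower without TP-3654 replicate 1 (median -0.85, adjusted p = 1.79e-07) or vehicle replicate 3 (adjusted p = 0.0199). For these calls the adjusted p was 0.74 and 0.92 with an estimated correlation. The megakaryocyte list was called lower without TP-3654 replicate 1 (adjusted p = 0.0276; adjusted p = 0.8 with an estimated correlation), with 2 members higher and 6 lower. The T, NK and innate lymphoid list was called higher without vehicle replicate 3 (adjusted p = 0.0404) or TP-3654 replicate 3 (adjusted p = 0.00648), where the adjusted p was 0.66 and 0.33 with an estimated correlation. Adjusted over that list alone, 3 rose and 2 fell without vehicle replicate 1, 2 rose and 1 fell without TP-3654 replicate 3, and 1 fell without TP-3654 replicate 2. In the megakaryocyte list 2 rose without vehicle replicate 1 and 1 without TP-3654 replicate 3. The B cell median was 0.84 without vehicle replicate 1, 0.43 without TP-3654 replicate 2 and -0.08 without TP-3654 replicate 1.

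Among proliferation genes, mitotic genes fell as a list (median -0.34, camera adjusted p = 8.39e-16; adjusted p = 0.58 with an estimated correlation). Of 55 members edgeR called 0 adjusted over the list alone and 0 over all genes, 26 had an unadjusted p under 0.05, all lower, and DESeq2 called 7. Leaving out TP-3654 replicate 1, 34 fell adjusted over the list alone, and leaving out TP-3654 replicate 3, 5 did. The mitotic kinesin Kif2c had a log2 fold change of -0.52 (SE 0.12), Cdc25c one of -0.67 (SE 0.19), the anaphase activator Cdc20 one of -0.56 (SE 0.16) and cyclin gene Ccnb2 one of -0.66 (SE 0.19). Replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, fell as a list (median -1.08, camera adjusted p = 8.33e-20; adjusted p = 0.58 with an estimated correlation). Of 58 members edgeR called 0 adjusted over the list alone and 0 over all genes, 33 had an unadjusted p under 0.05 and DESeq2 called 6. Leaving out TP-3654 replicate 2, 25 fell adjusted over the list alone. Hist1h2bc, with 32.6% of its 31-mers shared with another locus, stood at 16.3 and 9.59 CPM, and the median member shared 56.3%, so single histone genes are uncertain. The 57 genes of G1/S and DNA replication had a median of 0.05 (camera adjusted p = 0.755). In edgeR 0 passed adjusted over the list alone or over all genes, with 2 at an unadjusted p under 0.05, Msh6 (0.26) and Pole (0.36), and 0 called by DESeq2.

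The BCL2 family list fell (median -0.18, camera adjusted p = 0.0211; adjusted p = 0.76 with an estimated correlation), a call lost without vehicle replicate 2 (adjusted p = 0.0813) or TP-3654 replicate 3 (adjusted p = 0.0755), and for the latter also on genes with unique sequence (median -0.10, adjusted p = 0.147). Pmaip1, which encodes the pro-apoptotic protein Noxa, fell adjusted over the list alone (log2 fold change -1.14, SE 0.25). In edgeR 0 of 22 passed over all genes, and Bid (-0.36) and Birc5 (-0.45) were among 8 at an unadjusted p under 0.05, and DESeq2 called 2. Without vehicle replicate 2, vehicle replicate 3 or TP-3654 replicate 3 none passed. Pmaip1 had the smallest p also among 35 p53 target genes, where 0 passed adjusted over the list alone or over all genes, 6 had an unadjusted p under 0.05 and DESeq2 called 1. That list had a median of 0.01 and a mean of -0.02, and camera put it lower without a call (adjusted p = 0.625). Among 23 CDK inhibitors and quiescence genes, Txnip rose adjusted over the list alone and 0 passed over all genes (median -0.06, adjusted p = 0.588), with 4 at an unadjusted p under 0.05, among them Btg1 (-0.60), and 2 called by DESeq2. Without vehicle replicate 3 none passed, and without TP-3654 replicate 2, 3 also fell. The 65 MYC targets and ribosome biogenesis genes had a median of 0.05 (adjusted p = 0.569). In edgeR 0 passed adjusted over the list alone or over all genes, with 2 at an unadjusted p under 0.05, Mycn (0.88) and Utp20 (0.38), and 1 called by DESeq2. The 78 cytoplasmic ribosomal protein genes were called higher as a list (median 0.52, camera adjusted p = 0.0146; adjusted p = 0.98 with an estimated correlation). TP-3654 replicate 3 decided this call, since without it the list was called lower (median -0.13, adjusted p = 1.1e-05; adjusted p = 0.78 with an estimated correlation). The call was also lost without vehicle replicate 1 (adjusted p = 0.205) or vehicle replicate 2 (adjusted p = 0.0597), with limma-voom (median 0.34, adjusted p = 0.0516) and with its sample weights (median 0.01, adjusted p = 0.454). Here 0 members passed in edgeR or DESeq2, and 1, Rpl13a (-0.47), had an unadjusted p under 0.05.

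Among proteostasis and metabolic lists, the unfolded protein response genes fell as a list (median -0.40, camera adjusted p = 6.57e-10; adjusted p = 0.58 with an estimated correlation). Of 27 members, 13 fell adjusted over the list alone, against 0 over all genes, 15 at an unadjusted p under 0.05 and 9 called by DESeq2. The chaperone Calr fell from 2506 ± 151 to 1647 ± 259 CPM adjusted over the list alone (log2 fold change -0.61, SE 0.15), with the disulfide isomerase Pdia6 (-0.46, SE 0.11), the translocon subunit Sec61b (-0.40, SE 0.10) and Creld2 (-0.58, SE 0.16). The count was 0 without vehicle replicate 1, vehicle replicate 2 or TP-3654 replicate 1 and 6 without TP-3654 replicate 3, with a list median between -0.52 and -0.30. The mean log2 CPM of the list, centred per gene, was 0.377, 0.203 and -0.003 in vehicle replicates 1 to 3 and -0.245, 0.035 and -0.368 in TP-3654 replicates 1 to 3. The same score of the granulocyte-monocyte progenitor genes was 0.932, 0.533 and 0.291 in vehicle and -0.732, 0.025 and -1.049 in TP-3654 libraries, the same order of the 3 libraries within each group. The lysosomal genes fell as a list (median -0.23, camera adjusted p = 2.43e-05; adjusted p = 0.58 with an estimated correlation). Of 29 members 8 fell and 1 rose adjusted over the list alone, against 0 over all genes, 11 at an unadjusted p under 0.05 and 7 called by DESeq2. The cathepsin gene Ctsz (log2 fold change -0.79, SE 0.15), Hexa (-0.51, SE 0.11), the cholesterol carrier Npc2 (-0.56, SE 0.13) and the proton pump subunit Atp6v0d1 (-0.49, SE 0.12) fell and Cd63 (0.73, SE 0.22) rose. Without vehicle replicate 1 or 3 none passed, and without vehicle replicate 2 there were 4 lower. The lysosomal score was 0.230, 0.058 and 0.064 in vehicle and -0.156, 0.006 and -0.203 in TP-3654 libraries, with vehicle replicate 1 highest and TP-3654 replicate 3 lowest, as for the progenitor genes.

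The 75 nuclear-encoded oxidative phosphorylation genes fell as a list (median -0.24, camera adjusted p = 6.79e-09; adjusted p = 0.58 with an estimated correlation). In edgeR 0 members passed adjusted over the list alone or over all genes, with 18 at an unadjusted p under 0.05, all lower, and 1 called by DESeq2. Ndufa1 had a log2 fold change of -0.47, Uqcr11 one of -0.44, Ndufb5 one of -0.32 and Ndufb11 one of -0.34. The redox and NRF2 target list fell (median -0.12, camera adjusted p = 0.0117; adjusted p = 0.45 with an estimated correlation). The glutathione reductase gene Gsr fell adjusted over the list alone (-0.81, SE 0.17), 0 of 30 passed over all genes, and Pgd (-0.49), G6pdx (-0.42) and Gpx1 (-0.69) were among 6 at an unadjusted p under 0.05, while DESeq2 called 5. None passed without vehicle replicate 1, vehicle replicate 2 or TP-3654 replicate 1, and 3 fell without any 1 of the others. On genes with unique sequence the redox list call was lost with all 6 libraries (median -0.24, adjusted p = 0.066) and without TP-3654 replicate 3 (median -0.11, adjusted p = 0.172). The cholesterol synthesis list rose (median 0.26, camera adjusted p = 0.00989; adjusted p = 0.87 with an estimated correlation), a call lost without vehicle replicate 2 (median 0.14, adjusted p = 0.16). Of its 27 members edgeR called 0 adjusted over the list alone or over all genes, 9 had an unadjusted p under 0.05 and DESeq2 called 1. Adjusted over the list alone, 8 rose without vehicle replicate 1 and 6 without TP-3654 replicate 3. Its regulator Srebf2 had a log2 fold change of 0.44 (SE 0.11) and the enzyme gene Cyp51 one of 0.55 (SE 0.16). Hk3, a hexokinase (-0.78), fell adjusted over the list alone among 38 glycolysis and hypoxia genes (median 0.09, camera adjusted p = 0.932) and Vldlr (1.28) rose among 35 ATF4 and amino acid response genes (median -0.07, adjusted p = 0.625), with 0 of either list over all genes, 5 and 2 at an unadjusted p under 0.05 and 1 in each called by DESeq2. Hk3 did not pass without vehicle replicate 1 or 3, nor Vldlr without any 1 vehicle library or TP-3654 replicate 3. Of 21 heat shock genes, read as a sign of tissue handling, 0 passed in edgeR or DESeq2 and 1, Cacybp (-0.29), had an unadjusted p under 0.05 (median -0.11, camera adjusted p = 0.136). Camera called that list lower without vehicle replicate 3 (adjusted p = 0.00792), TP-3654 replicate 1 (adjusted p = 0.0369) or TP-3654 replicate 3 (adjusted p = 0.0234). For these calls the adjusted p was 0.66, 0.74 and 0.72 with an estimated correlation.

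Among inflammatory and signalling lists, the type I interferon genes were called higher (median 0.22, camera adjusted p = 0.0481; adjusted p = 0.98 with an estimated correlation). That call was lost without vehicle replicate 2 (adjusted p = 0.543), TP-3654 replicate 1 (adjusted p = 0.152) or TP-3654 replicate 3 (adjusted p = 0.374). It was also lost with upper-quartile factors (adjusted p = 0.057), library size alone (adjusted p = 0.0589), the stricter filter (adjusted p = 0.0594), limma-voom (adjusted p = 0.056) and genes with unique sequence (median 0.06, adjusted p = 0.861). Of 50 members 0 passed in edgeR adjusted over the list alone or over all genes, 6 had an unadjusted p under 0.05 and DESeq2 called 4. Ddx58 (0.59), Slfn8 (0.57) and Slfn5 (1.09) were higher and Ly6e (-0.47) lower in each TP-3654 library than in any vehicle library. The TNF and NF-kB list fell (median -0.09, camera adjusted p = 0.0342; adjusted p = 0.58 with an estimated correlation). Tlr2 (-0.65), Cd69 (-0.54) and Tnip1 (-0.38) were lower in each TP-3654 library than in any vehicle library. Of 46 members 0 passed in edgeR adjusted over the list alone or over all genes, 11 had an unadjusted p under 0.05 and DESeq2 called 6. Without vehicle replicate 2, 1 member fell adjusted over the list alone, and without TP-3654 replicate 2, 5 did. That list call was lost without vehicle replicate 1 (adjusted p = 0.0742), vehicle replicate 3 (adjusted p = 0.104) or TP-3654 replicate 1 (adjusted p = 0.0906), and with the stricter filter (adjusted p = 0.0602) or limma-voom (adjusted p = 0.0559). The WNT list rose (median 0.21, camera adjusted p = 0.00587; adjusted p = 0.45 with an estimated correlation). Znrf3 (0.84, SE 0.17) and the receptor gene Fzd6 (0.87, SE 0.19) rose adjusted over the list alone, 0 of 37 passed over all genes, 9 had an unadjusted p under 0.05 and DESeq2 called 3. None passed without vehicle replicate 2 or TP-3654 replicate 2, and only 1 without vehicle replicate 3.

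Of 29 profibrotic mediators and matrix genes (median -0.16, camera adjusted p = 0.608), the collagens Col4a1 (log2 fold change 1.10, SE 0.19) and Col4a2 and the gelatinase Mmp2 (1.67, SE 0.37) rose and Lgals1 fell adjusted over the list alone, with 0 over all genes, 6 at an unadjusted p under 0.05 and 4 called by DESeq2. Tgfb1, which encodes the cytokine TGF-beta 1, had a log2 fold change of -0.48 (SE 0.16) and was chosen after its value was seen. Ltbp3 (0.84), which binds latent TGF-beta, and Klf10 (0.61) rose among 36 TGF-beta and BMP genes (median 0.17, camera adjusted p = 0.105) adjusted over the list alone, and Klf10 also among 31 AP-1 and immediate early genes (median -0.36, adjusted p = 0.209), with 0 of either list over all genes, 11 and 3 at an unadjusted p under 0.05 and 2 and 1 called by DESeq2. Without vehicle replicate 2 or 3 no TGF-beta and BMP member passed, and without TP-3654 replicate 3 that list was called higher (adjusted p = 0.0311; adjusted p = 0.72 with an estimated correlation). No AP-1 member passed without vehicle replicate 1, vehicle replicate 3, TP-3654 replicate 1 or TP-3654 replicate 2, and without vehicle replicate 2 that list was called lower (median -0.64, adjusted p = 8.43e-07; adjusted p = 0.69 with an estimated correlation). In 4 further lists 0 members passed in edgeR adjusted over the list alone or over all genes. Among them were 27 interferon-gamma genes (median 0.11, camera adjusted p = 0.99), where Cd274 stood at 0.60 and Irf8 at -0.64, and 20 MHC class I genes (-0.08, adjusted p = 0.209), where H2-D1 stood at -0.44. The others were 14 MHC class II genes (-0.03, adjusted p = 0.976), where H2-Ob stood at 0.60, and 32 chemokines and receptors (-0.03, adjusted p = 0.423), where Il18 stood at 1.17 and Ccl9 at -0.94. At an unadjusted p under 0.05 these lists had 4, 3, 1 and 7 members, and DESeq2 called 2, 1, 0 and 4. Adjusted over the list alone without TP-3654 replicate 1, 1 interferon-gamma gene and 1 MHC class II gene rose, and 1 chemokine gene rose and 2 fell. Without TP-3654 replicate 3, 2 interferon-gamma genes and 1 chemokine gene fell, and 1 chemokine gene rose without vehicle replicate 1 and 1 fell without vehicle replicate 2. The mean was 0.03 for MHC class I and 0.04 for MHC class II, opposite in sign to the medians, and camera called the MHC class I list lower without vehicle replicate 1 (adjusted p = 0.0178) or TP-3654 replicate 3 (adjusted p = 0.00117). For these calls the adjusted p was 0.83 and 0.72 with an estimated correlation. Over the 39 lists together, edgeR made 99 calls adjusted over the list alone, 37 without vehicle replicate 2 and 62 without vehicle replicate 3, and limma-voom called 0 members over all genes.

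By camera with the preset correlation, 5 lists rose and 11 fell, while with an estimated correlation 0 lists passed, and fry called 1, the redox and NRF2 targets. TP-3654 replicate 3 stood apart from the other libraries. It lay at least 2-fold above or below all 5 others at 537 genes, where the next highest library did so at 88. Ribosomal protein genes took 8.87% of its counts and 4.53% to 5.31% of the others. Rps7 had 30287 counts there and 3615 to 4502 elsewhere, and the retrocopies Aldoart2 and Prdx6b had 0 counts there, named after their values were seen. Erythroid genes lay at a median log2 CPM of -1.45 against the mean of the other libraries, and mast cell, basophil and eosinophil genes at -0.70.

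**Figure D3:**
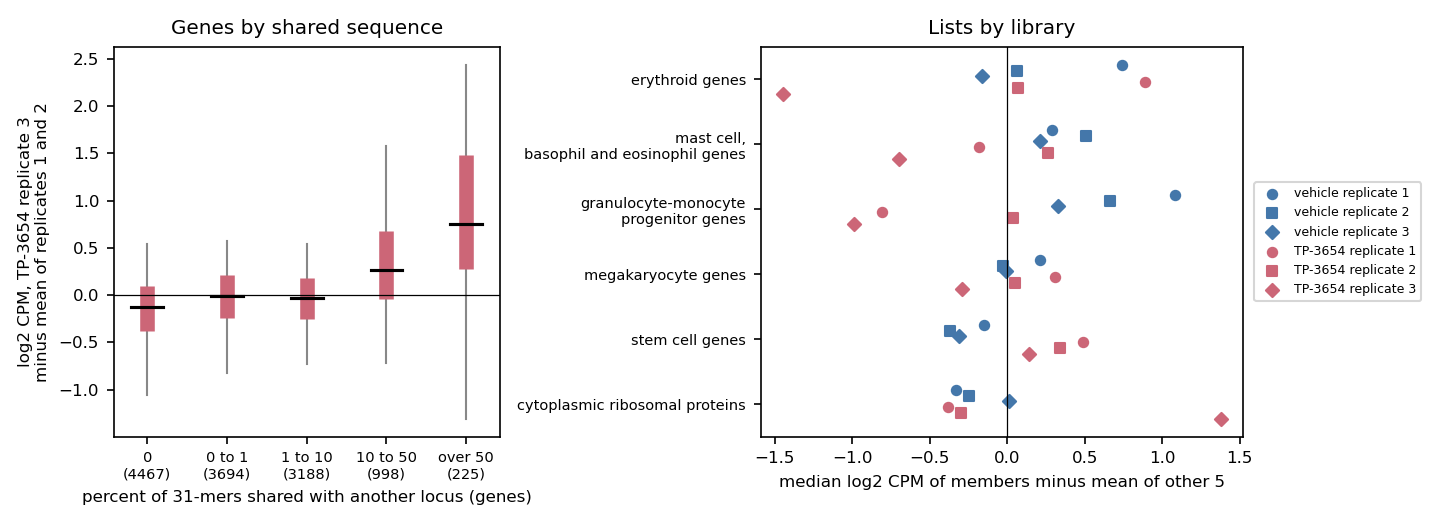
Left, log2 CPM of TP-3654 replicate 3 minus the mean of TP-3654 replicates 1 and 2 (y axis) for genes binned by the percent of 31-mers shared with another locus, with the number of genes in brackets; black lines are medians, red bars quartiles and grey lines the range from the 5th to the 95th percentile. Right, median log2 CPM of list members in each library minus the mean of the other 5 (x axis), where the median difference was 0.75 in genes with over 50% shared and -0.13 in genes with none, and TP-3654 replicate 3 lay at 1.38 for ribosomal proteins and -1.45 for erythroid genes.

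The authors' deposited table of the same comparison lists 13154 genes and calls 699 at an adjusted p under 0.05, 374 higher and 325 lower. It calls 18 of 34 granulocyte-monocyte progenitor genes lower, 12 of 45 stem cell genes higher and 10 of 27 unfolded protein response genes lower. For 2 lists called higher here its median has the other sign. These are the type I interferon genes (-0.05, against 0.22 in edgeR) and the ribosomal protein genes (-0.16, against 0.52). Of 23 STAT5 target genes it calls 0, with a deposited adjusted p of 0.293 for Cish and 0.224 for Pim2. Of the 690 genes called in the authors' deposited table and tested here, 684 had the same sign in edgeR and 655 also an unadjusted p under 0.05, with 0 called by edgeR over all genes. DESeq2 on the deposited counts made 657 calls and shared 467 with the 699 of the authors' deposited table in the same direction. Independent lists would share 17.6, a figure of little weight here because both lists describe the same 6 samples. Across 12793 genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of edgeR had a Pearson r of 0.903 and a Spearman rho of 0.875, and 0.965 and 0.955 without TP-3654 replicate 3. The mean normalized count in the authors' deposited table came within 1% of the mean recomputed from the deposited counts for 304 of 12993 genes, with a median ratio of 0.879. After division by that ratio 1106 came within 1%, so a common scale factor alone did not account for the difference from the authors' deposited table. For Rps7 the authors' deposited table has a log2 fold change of -0.02, where edgeR on the deposited counts gave 1.88.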

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

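The fits restricted to genes with unique sequence, and camera with an estimated correlation leaving out 1 library, were chosen after seeing the data. Named genes kept their sign under each alternative run: 2599 comparisons kept their side of the threshold and 189 moved past it. Since edgeR called 0 genes in the main fit, a kept side means still not called, and a move could only be toward a call. Most of these genes were also picked by smallest p in the same libraries. For the 16 called lists, 256 comparisons kept direction and call, 57 lost the call and in 3 camera's direction turned. In edgeR the 0 genes called became 4 higher and 1 lower without a low-count filter, 1 higher and 2 lower with a replicate block, and 173 higher and 77 lower at an FDR of 0.1. DESeq2 called 401 higher and 256 lower, and limma-voom with sample weights called 101 and 46. The genes with unique sequence gave 77 higher and 44 lower, and 25 and 14 without TP-3654 replicate 3. Leaving out 1 library gave 0 to 19 higher and 0 to 13 lower genes. The 5 lists called higher became 3 with limma-voom, 8 with sample weights, 3 with unique sequence, 8 with unique sequence without TP-3654 replicate 3, 8 at an FDR of 0.1, and 0 with an estimated correlation or fry, with a range of 2 to 7 when leaving out 1 library. The 11 lists called lower became 7 with unique sequence without TP-3654 replicate 3, 0 with an estimated correlation and 1 with fry. The ribosomal and histone lists had too few members with unique sequence to be tested. Calls shared with the authors' deposited table went from 0 in edgeR to 467 in DESeq2. The 99 calls adjusted over the list alone became 207 in DESeq2 and 168 with sample weights, and ranged from 37 to 139 when leaving out 1 library. In camera's direction, but with a positive median and no call, the type I interferon list turned with unique sequence without TP-3654 replicate 3 (median 0.03, adjusted p = 0.944) and the ribosomal list with sample weights (median 0.01, adjusted p = 0.454). The ribosomal median ranged from -0.13 to 0.77 when leaving out 1 library, and only without TP-3654 replicate 3 was that list called lower. With an estimated correlation no list passed when leaving out 1 library (smallest adjusted p 0.33). For these alternatives the cause was not tested. Replicate numbers did not pair libraries: deviations from group means had an r of -0.012, -0.015 and 0.031 across genes, which are not independent replicates. Depth limits detection to 0.119 to 0.146 CPM for 3 counts, by counting error only.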

Other observations

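The tests of shared sequence, of the different counting of TP-3654 replicate 3, of mature myeloid cells, of the stem cell share and of G1/S genes, and the splits counting genes at an FDR of 0.05, were chosen after the result was seen.

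The Gimap genes, a cluster of GTPases of the immune system, were chosen after the value of Gimap5 was seen, so p-values adjusted over the family alone were computed but carry no weight and are left out. All 8 tested members had a positive log2 fold change, and edgeR called 0 of them over all genes. The values were 1.45 (SE 0.22) for Gimap8, 1.38 (SE 0.35) for Gimap3, 1.35 (SE 0.18) for Gimap5, 0.71 (SE 0.15) for Gimap6 and 0.51 (SE 0.13) for Gimap9. Gimap1 (0.42), Gimap4 (0.33) and Gimap7 (0.29) had smaller values, and Gimap6 and Gimap1 are also in the stem cell list.

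TP-3654 replicate 3 lay outside the other 5 libraries at many genes. Sharing of sequence with other loci did not account for the whole pattern, since those genes shared a median of 1.9% of their 31-mers, although 39.8% of them shared over 10%. Among genes with unique sequence this library still lay 2-fold outside at 202, against 60 in the next, consistent with cells of another type or degraded RNA. Its ribosomal protein genes and retrocopies are consistent with reads shared with copies being counted differently, as 45.3% of genes with over 50% shared sequence differed 2-fold from replicates 1 and 2, against 7.2% of genes with none. Different counting was argued against for erythroid and mast cell genes, whose 49 members with unique sequence had a median difference of -1.33, with Klf1, chosen after its values were seen, at 5.88 CPM there and 46.3 to 97.7 elsewhere, so a sort with fewer such progenitors and an effect of the drug in that sample stay open and untested.

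Granulocyte-monocyte progenitor genes were lower and stem cell genes higher with TP-3654 by camera at its preset correlation (adjusted p = 0.45 with an estimated correlation for each). The different counting of TP-3654 replicate 3 was argued against as the whole cause, since without it the progenitor median was -1.05. Mature myeloid cells in the vehicle sorts were argued against too, as the whole cause. The summed CPM of S100a8, S100a9, Camp, Ngp and Ltf was lower in 2 vehicle libraries than in at least 1 TP-3654 library. Vehicle replicate 1 had the highest sum, 108 CPM against at most 21 in a TP-3654 library, so such cells there stay open. Without that library the progenitor median was -0.89. Adjusted over the list alone, 4 progenitor members then fell instead of 25, and 23 stem cell members rose instead of 19. A larger share of long-term stem cells at the cost of all other progenitors cannot be told apart from a change within cells: the lymphoid-primed score differed by 0.25 toward TP-3654, with 2 of 3 TP-3654 libraries above all vehicle libraries. An effect of PIM inhibition on the make-up of the sorted fraction may underlie the pattern and was not tested separately from one within cells.

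Replication-dependent histone genes were lower with TP-3654 as a list by camera at its preset correlation (adjusted p = 0.58 with an estimated correlation), with 0 of 58 members passing in edgeR adjusted over the list alone or over all genes, 33 at an unadjusted p under 0.05 and 6 called by DESeq2. Counting of histone copies in TP-3654 replicate 3 was argued against as the whole cause, since the median without it was -0.94. Less carry-over of RNAs that lack a poly(A) tail stays open: 27 small RNA genes had a median of 0.18, which met the bound set beforehand for excluding it. This bound was set aside after the result was seen, because 20 of the 27 lie inside other genes whose reads can supply their counts. The histone score was 0.153, 0.348 and 0.99 in vehicle replicates 1 to 3 and -0.77 to -0.067 in TP-3654 libraries. Without vehicle replicate 3 the histone median was -0.7, so the size of the fall depended on that library. The most counted gene of that library, which has no symbol here, took 1.06% of its counts, while Eef1a1 ranked first in each other library. Whether the RNA of that gene lacks a poly(A) tail was not tested. Fewer cells replicating DNA was argued against as the whole cause, since G1/S genes had a median of 0.05 (quartiles -0.07 and 0.14) against -1.08 for histones, while a share of the change stays open.

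Splitting the 6 libraries 3 against 3 gives 10 splits, too few for a share under 0.05. At an FDR of 0.05 the real split and the highest other both gave 0 genes by edgeR, so 10 of 10 splits gave as many, with 2244 genes at an unadjusted p under 0.05 and 657 by DESeq2 in the real split. At an unadjusted p under 0.05 the real split gave 2244 genes and the highest other 458, so 1 of 10 gave as many. Camera called 16 lists in the real split and 23 in the highest other, and 4 of 10 gave as many. Of those 16, type I interferon (0.302 against 0.217) and ribosomal protein genes (0.715 against 0.518) had a larger absolute median in another split. So did TNF and NF-kB (0.113 against 0.092), BCL2 family (0.181 against 0.177) and mast cell, basophil and eosinophil genes (0.548 against 0.484). The rest had their largest absolute median in the real split. The margin was narrow for unfolded protein response (0.397 against 0.393) and mature neutrophil and monocyte genes (1.02 against 1.019). It was also small for lysosomal (0.231 against 0.224), redox and NRF2 (0.116 against 0.107) and cholesterol synthesis genes (0.262 against 0.242). The same held for oxidative phosphorylation (0.237 against 0.214) and mitotic genes (0.336 against 0.298). The granulocyte-monocyte progenitor list had 25 members passing adjusted over the list alone and the stem cell list 19, against 0 in any other split. Other lists had more members passing in another split than in the real one: AP-1 genes 8 against 1, mature neutrophil and monocyte genes 4 against 1, erythroid genes and MHC class II genes 4 against 0, heat shock genes 2 against 0, and T, NK and innate lymphoid genes 1 against 0.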
